A study of Bacillus subtilis subsp. subtilis NCIB 3610 = ATCC 6051 = DSM 10 with 28 samples.

How the data were processed

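Gene counts of 28 libraries from biofilm colonies were taken from 2 deposited tables, each a table of read counts per gene and library. According to the submitters' processing notes, reads were trimmed with cutadapt, mapped with Bowtie2 2.3.4.1 and counted with HTSeq, and DESeq2 1.16 was used for the authors' own tests. The genome build is not given in the sources used here. The library kit is directional, and the strand setting of the counting is not stated. Per the labels, RNA was total RNA from colonies at 30°C on B4 medium with 0.25% calcium acetate or without, and nothing says whether the numbered libraries are separate cultures. The p-values therefore measure only the spread between libraries, which may be technical.

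The table of medium and age held 4348 rows for 22 libraries in 8 groups of 2 or 3. Every value in it was even, so that 1 read may have been counted as 2, and each count halved was added as an alternative. In 26 rows the values of the 16 libraries of days 1, 2 and 3 were blank, and these were left out, leaving 4322. The cueR table held 4317 rows for 6 libraries, of which 78 carried no gene name and were left out. Those unnamed rows held 0.00858 to 0.0175% of counts, and rRNA and tRNA genes (135 rows) 13.3 to 29.9%. Totals were 660560 to 7986390 (median 3009517) in the first table and 1010272 to 2525390 in the cueR table, and the 10 most abundant genes took 11.6 to 38.9% and 18.7 to 34.6% of counts. CPM values divide by the library size times its TMM factor, and list shares are percent of counts outside rRNA and tRNA.

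Samples were grouped from their titles and labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM factors, a quasi-likelihood fit and F-tests, with Benjamini-Hochberg adjustment over the genes tested (4190 and 3759) and a threshold of 0.05. The 22 libraries shared one fit of 8 groups. Contrasts were calcium against no calcium at each of the 4 days and as their equally weighted mean, the difference of that effect between days (3 contrasts at once), and day 6 against day 1 in each medium. The 6 cueR libraries were fitted alone. Errors after a log2 fold change are standard errors from the F-statistic, and those after CPM or shares are SD. Every adjusted p for a gene is from edgeR unless DESeq2 is named. Where a group had no counts, a bound was computed against a floor of 6 counts per library in the first table, whose values are even, and 3 in the cueR table.

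A set of 36 gene lists was fixed from textbook knowledge before the data were examined, as were the comparisons, their tests, most alternatives and the rule for named genes. Lists with at least 4 tested members (35) were compared with all other genes by camera of limma 3.58.1 with the preset correlation of 0.01, adjusted over the lists of a comparison. The estimated correlation and fry were alternatives. The rule named called genes with a mean CPM of at least 10: the 10 highest and 10 lowest for the mean of 4 days and for cueR, 5 at each end for single days and ages, and the 5 of lowest p for the difference between days. It also named up to 3 called members of lowest adjusted p per list with the lowest in the other direction, and, called or not, cueR, copA, copZ, csoR, the lcfA operon, tasA and epsA. The text gives values for only part of the genes so named, chosen after their values and stability were seen, mostly those first in order that carry a gene symbol. Overlaps were tested with 2-sided Fisher's exact tests, adjusted over 8 tests. The camera calls that held with an estimated correlation were early and late sporulation at day 1, those and PerR at day 2, late sporulation and PerR at day 3 and in the mean, PerR at day 6, early and late sporulation with age without calcium, SOS and polyglutamate with age on calcium, and none for cueR.

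Alternatives were DESeq2 size factors, upper quartile factors, no filter, a filter of 50 counts in 2 libraries, a robust spread, a 2-fold minimum, no rRNA and tRNA rows, the number in the titles as a block, the compared groups alone, DESeq2 1.42.0, and each library left out in turn. Chosen after the data were seen were halved counts, library sizes only, and leaving out the 4 shallowest libraries together. The number in the titles marks a set in the larger table, and what a set shares is not stated. Residuals of same-numbered libraries across media correlated at 0.0326 to 0.407 (10 pairs, 3 at 0.1 or below), yet the shared fit had no block. At days 1 (0.327 and 0.340) and 6 (0.188, 0.275 and 0.185) all pairs lay above 0.1, and blocked counts are given. The pipeline was tested on simulated data in which 2, 4 and 8-fold changes were planted: edgeR recovered 20.9, 83.6 and 95.5% at day 1, 10.4, 92.5 and 98.5% at day 2, 10.4, 80.6 and 95.5% at day 3, 25.4, 89.6 and 97.0% at day 6 and 73.1, 98.5 and 100% in the mean. It recovered 2.99, 52.2 and 89.4% for the difference between days, 23.9, 86.6 and 93.9% and 8.96, 71.6 and 90.9% for age without and with calcium, and 5.97, 83.6 and 92.4% for cueR, so that 2-fold changes at a single day were mostly missed. With 66 or 67 genes changed per fold, 2 to 13 of 3956 unchanged genes (calcium contrasts) and 5 of 3505 (cueR) were called. Random lists (0 of 100 called) do not test correlation within real ones.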

Results

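Transcript counts were measured in biofilm colonies of an undomesticated Bacillus subtilis strain that builds structured colonies and spores. Colonies grew on B4 medium, a yeast extract and glucose agar, in a closed box whose air a burning candle had enriched in CO2. The medium either held 0.25% calcium acetate or none. No group had acetate without calcium, so effects of calcium and of acetate cannot be told apart. Below, calcium stands for calcium acetate. Wild-type colonies were sampled at 1, 2, 3 and 6 days in 22 libraries. Each medium and day had 3 libraries, except 2 with calcium at day 1 and 2 without calcium at day 3. A separate table held 6 libraries of calcium-grown colonies at day 3, 3 of a strain deleted for cueR and 3 of the wild type. CueR is a regulator of the MerR family that responds to copper. Total counts were 660560 to 7986390 per library in the larger table and 1010272 to 2525390 in the cueR table. The 4 shallowest libraries of the larger table were replicate 1 of calcium at each of the 4 days. Within groups, all 26 pairs of replicates differed by more than sampling noise (lowest chi-square per degree of freedom 6.83), and their log2 CPM correlated at r = 0.808 to 0.979.

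The first question was what calcium in the medium changes in colony gene expression, averaged over the 4 days. Spore genes rose and genes of the response to peroxide fell. Catalase gene katA dropped from 24596 ± 1414 CPM without calcium to 264 ± 51.7 CPM with calcium at day 2 (SD, n = 3 each), and its mean fold over the 4 days was 46.2 (log2 fold change -5.53 ± 0.33, adjusted p = 1.5e-11). Dipicolinate synthase gene spoVFB, which makes a compound stored in spores, went from 6.60 ± 0.516 to 567 ± 92.4 CPM at day 2 (mean log2 fold change 4.62 ± 0.18, adjusted p = 2.4e-13). Of 4190 genes tested, 2629 were called, 1344 higher and 1285 lower with calcium, and 934 and 566 of them changed at least 2-fold. With library sizes only, without a correction for composition, the called genes were 985 higher and 1571 lower. Lower calls were also more numerous with upper quartile factors (1282 and 1341), the stricter filter (1189 and 1331), halved counts (1259 and 1379) and on leaving out 12 of the 22 libraries singly. The highest named changes were cotC (6.85 ± 0.76, adjusted p = 1.3e-07), yosA (6.61 ± 0.47, adjusted p = 1.7e-10), yhdB (6.55 ± 0.61, adjusted p = 1.1e-08) and sspJ (6.45 ± 0.75, adjusted p = 2.7e-07), where cotC encodes a spore coat protein and sspJ a small acid-soluble spore protein. The sspO gene also ranked among them, and no fold is given because it had no counts without calcium at day 1. At the other end stood mrgA (-5.45 ± 0.42, adjusted p = 5.5e-10), yhbE (-4.84 ± 0.22, adjusted p = 1.0e-12), ahpF (-4.52 ± 0.27, adjusted p = 1.7e-11) and ahpC (-4.46 ± 0.27, adjusted p = 1.7e-11) beside katA. MrgA binds DNA and stores iron, and AhpC and AhpF form alkyl hydroperoxide reductase.

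Gene lists fixed from textbook knowledge were then compared with all other genes. Here and below, medians of lists are those of the log2 fold changes of their tested genes. Late sporulation genes of sigma G, sigma K and the coat rose together, 42 higher, 0 lower and 0 not called (median 4.13, camera adjusted p = 2.9e-28, 0.018 with estimated correlation), with cgeB (5.43 ± 0.27) and cotA (3.72 ± 0.18) as examples. Early sporulation genes of sigma F and sigma E followed, 23 higher, 0 lower and 2 not called (median 2.60, camera adjusted p = 4.9e-11, 0.057 with estimated correlation), and their median was 2.44 with the member lacking counts in a group set to its bound. Members included safA (3.07 ± 0.17) and spoIVA (2.87 ± 0.17), a coat assembly and a coat anchoring gene. The biofilm matrix list, exopolysaccharide and amyloid fibre genes, had 19 higher, 0 lower and 0 not called (median 1.80, camera adjusted p = 1.5e-07, 0.16 with estimated correlation). In it, tapA (3.39 ± 0.22), epsB (2.47 ± 0.16), tasA (2.66 ± 0.27) and epsA (2.22 ± 0.27) all rose, and tasA encodes the main fibre protein. The skf and sdp cannibalism genes, which make toxins against sister cells, had 11 higher, 0 lower and 0 not called (median 1.58, camera adjusted p = 0.0058, 0.45 with estimated correlation), among them skfB (1.86 ± 0.18). Flagella and chemotaxis genes fell, 0 higher, 36 lower and 3 not called (median -1.29, camera adjusted p = 2.8e-10, 0.31 with estimated correlation), for example flgK (-1.53 ± 0.14) and flgE (-2.00 ± 0.19). The PerR peroxide stress list fell throughout, 0 higher, 13 lower and 0 not called (median -2.40, camera adjusted p = 3.4e-13, 0.018 with estimated correlation). Iron uptake genes of the Fur regulon had 1 higher, 15 lower and 15 not called (median -0.42, camera adjusted p = 0.0058, 0.86 with estimated correlation), with efeU (-2.28 ± 0.19) as the lowest p. SOS and PBSX prophage genes had 0 higher, 26 lower and 6 not called (median -1.27, camera adjusted p = 1.7e-05, 0.59 with estimated correlation), including recA, the recombinase of DNA repair (-1.60 ± 0.14), and uvrA (-1.77 ± 0.16). At day 1, however, the median of that list was 0.90, against -1.12, -2.80 and -2.33 at days 2, 3 and 6. TCA cycle genes had 1 higher, 9 lower and 4 not called (median -0.46, camera adjusted p = 0.031, 0.72 with estimated correlation), with sdhB of succinate dehydrogenase at -1.71 ± 0.13 and citZ at 0.48 ± 0.14. The list medians with library sizes only were -0.65 for iron uptake and -0.79 for the TCA cycle. Gluconeogenesis and glycolysis genes had 0 higher, 10 lower and 4 not called (median -0.89, camera adjusted p = 0.0095, 0.72 with estimated correlation), such as fbp (-1.39 ± 0.16). The highest adjusted p of these members was 0.0046 for citZ. The call of citZ was lost with library sizes only (adjusted p = 0.34).

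No call came from camera for the lists closest to calcium and carbonate, whose members lay on both sides of 0. Calcium and other divalent cation transport had 7 higher, 7 lower and 1 not called (camera adjusted p = 0.18). The manganese importer genes mntC (-2.90 ± 0.17) and mntB (-2.90 ± 0.17) fell and yloB, a calcium-transporting ATPase gene, rose (2.26 ± 0.14). Of the lcfA operon, genes of fatty acid activation and oxidation that were tested for calcite formation in earlier work, etfA (-0.82 ± 0.14, adjusted p = 4.3e-05) and etfB (-0.68 ± 0.16, adjusted p = 0.0012) were lower, and lcfA (0.26 ± 0.13, adjusted p = 0.10), fadR (0.15 ± 0.15, adjusted p = 0.38) and fadB (-0.24 ± 0.18, adjusted p = 0.25) were not called, with camera adjusted p = 0.54. The gene lcfA passed the threshold with DESeq2 (adjusted p = 0.042) and without the 4 shallowest libraries (adjusted p = 0.0083). The gene fadB passed the threshold without calcium day 1 replicate 2 (adjusted p = 0.022) and with library sizes only (adjusted p = 0.0075). Across single days lcfA ranged from 0.08 to 0.47, fadR from -0.14 to 0.39 and fadB from -0.69 to 0.22, with 0 days called. The etfA gene ranged from -1.01 to -0.60 and etfB from -0.87 to -0.55, with etfA called at days 2 and 3 and etfB at day 3. Day by day, some of these calls turned on 1 library. At day 1: The gene lcfA passed the threshold without the 4 shallowest libraries (adjusted p = 0.047). The gene etfB passed the threshold without no calcium day 1 replicate 2 (adjusted p = 0.047). The gene etfA passed the threshold without no calcium day 1 replicate 2 (adjusted p = 0.016), without calcium day 1 replicate 2 (adjusted p = 0.043), with the stricter filter (adjusted p = 0.047), with a robust spread (adjusted p = 0.049), with DESeq2 (adjusted p = 0.038) and with each count halved (adjusted p = 0.046). At day 2: The gene etfB passed the threshold with upper quartile factors (adjusted p = 0.049). At day 3: The gene fadB passed the threshold with library sizes only (adjusted p = 0.027). The call of etfB was lost without no calcium day 3 replicate 1 (adjusted p = 0.21), without no calcium day 3 replicate 3 (adjusted p = 0.056), without calcium day 3 replicate 1 (adjusted p = 0.12), without calcium day 3 replicate 2 (adjusted p = 0.097) and without the 4 shallowest libraries (adjusted p = 0.14). The call of etfA was lost without no calcium day 3 replicate 3 (adjusted p = 0.086), without calcium day 3 replicate 1 (adjusted p = 0.063) and without calcium day 3 replicate 2 (adjusted p = 0.076). At day 6: The gene etfB passed the threshold with library sizes only (adjusted p = 0.042). The gene etfA passed the threshold with library sizes only (adjusted p = 0.037). Fatty acid degradation genes had 0 higher, 4 lower and 7 not called (camera adjusted p = 0.40), among them fadA (-0.95 ± 0.20). Of 3 carbonic anhydrase genes 2 were higher, too few for camera. Urease and nitrogen genes had 3 higher, 9 lower and 7 not called (camera adjusted p = 0.28), with glnK (-1.08 ± 0.16), amtB (-2.03 ± 0.32) and glnR (1.35 ± 0.23). Copper genes had 0 higher, 3 lower and 6 not called (camera adjusted p = 0.41), for example ycnI (-0.88 ± 0.18), and zinc genes 2 higher, 2 lower and 6 not called (camera adjusted p = 0.65), for example zosA (-3.64 ± 0.27) and czrA (0.82 ± 0.17). The highest adjusted p of the called members outside the lcfA operon was 4.3e-04 for fadA.

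Of the lists on stress and synthesis, phosphate starvation genes under PhoP had 11 higher, 1 lower and 7 not called (camera adjusted p = 0.33), with ydhF (1.90 ± 0.23) and the alkaline phosphatase gene phoA at 1.66 ± 0.22. General stress genes under sigma B had 1 higher, 8 lower and 15 not called (camera adjusted p = 0.33). Of these, csbC stood at -2.24 ± 0.48. Protein quality control genes had 5 higher, 5 lower and 5 not called (camera adjusted p = 0.70), with lonA (-0.81 ± 0.12) and hrcA (0.77 ± 0.14). Cell envelope stress genes had 4 higher, 8 lower and 12 not called (camera adjusted p = 0.41), with dltE (-1.57 ± 0.15) and sigX (0.89 ± 0.16). Ribosomal protein genes had 7 higher, 5 lower and 35 not called (camera adjusted p = 0.89), with rpsI (-1.09 ± 0.19) and rpsT (1.83 ± 0.36). Purine genes had 6 higher, 2 lower and 11 not called (camera adjusted p = 0.97), with guaB, the IMP dehydrogenase gene, at -2.73 ± 0.16 and pbuG at 1.23 ± 0.21. Pyrimidine genes had 7 higher, 0 lower and 4 not called (camera adjusted p = 0.61). Of these, pyrB stood at 1.93 ± 0.34. Arginine synthesis genes had 7 higher, 0 lower and 2 not called (camera adjusted p = 0.33). Of these, argC stood at 1.18 ± 0.17. Arginine and ornithine degradation genes had 1 higher, 3 lower and 3 not called (camera adjusted p = 0.54). Of these, rocG stood at -1.03 ± 0.21. The highest adjusted p of these members was 4.2e-04 for csbC.

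The remaining lists were not called either. Biofilm regulators had 6 higher, 3 lower and 3 not called (camera adjusted p = 0.89), with the kinase gene kinD at -1.32 ± 0.11 and sinI, the antirepressor of the matrix genes, at 2.66 ± 0.35. Competence genes had 3 higher, 3 lower and 8 not called (camera adjusted p = 0.70), with comEB (-1.42 ± 0.15) and the master regulator comK at 1.49 ± 0.25. Acetate and acetoin genes had 2 higher, 6 lower and 7 not called (camera adjusted p = 0.37), with acsA (-1.24 ± 0.14) and ywbG (1.11 ± 0.26). Anaerobic and low oxygen genes had 4 higher, 5 lower and 14 not called (camera adjusted p = 0.61), with the lactate dehydrogenase gene ldh at -1.56 ± 0.21. Branched-chain amino acid genes had 1 higher, 2 lower and 7 not called (camera adjusted p = 0.46). Of these, ilvD stood at -1.71 ± 0.14. Surfactin and other peptide or polyketide genes had 10 higher, 2 lower and 25 not called (camera adjusted p = 0.65). Of these, albG stood at 1.85 ± 0.18. Extracellular protease genes had 6 higher, 3 lower and 2 not called (camera adjusted p = 0.58), with the subtilisin gene aprE at 2.28 ± 0.16 and epr at -1.54 ± 0.15. Polyglutamate genes had 0 higher, 2 lower and 4 not called (camera adjusted p = 0.40). Of these, pgdS stood at -1.92 ± 0.15. Osmoprotectant genes had 4 higher, 10 lower and 9 not called (camera adjusted p = 0.54). Of these, proJ stood at 2.83 ± 0.16. Sulfur and cysteine genes had 11 higher, 2 lower and 13 not called (camera adjusted p = 0.23). Of these, ssuA stood at 2.52 ± 0.27. The highest adjusted p of these members was 9.8e-04 for ywbG. Adjusted over the list alone, the counts for the mean of 4 days were the same except in copper (0 higher and 2 lower), general stress (1 higher and 6 lower), ribosomal proteins (5 higher and 5 lower), surfactin and other products (7 higher and 0 lower) and sulfur and cysteine (10 higher and 2 lower). The camera test pointed down against a positive median for competence, divalent cation transport, zinc, anaerobic and low oxygen, protein quality control, cell envelope stress and ribosomal proteins. Of these, the mean was also negative for divalent cation transport (-0.72), anaerobic and low oxygen (-0.06) and cell envelope stress (-0.15).

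**Figure D1:**
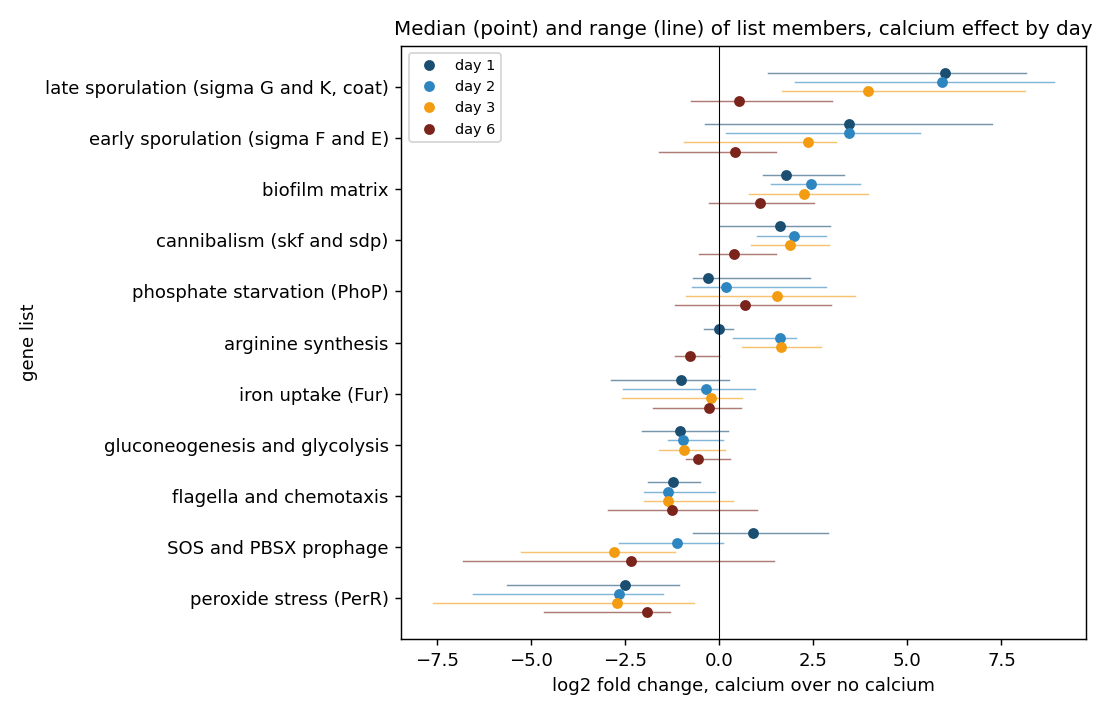
Median log2 fold change, calcium over no calcium, of 11 gene lists on the horizontal axis (points), with a line over the range of each list's members and one colour for each colony age of 1, 2, 3 and 6 days. Late sporulation medians were 6.00, 5.91 and 3.96 at days 1, 2 and 3 and 0.54 at day 6, where library sizes only gave -0.03, and PerR medians were -2.49, -2.67, -2.70 and -1.91.

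At day 1 the question was what calcium changes in young colonies (n = 2 with calcium, 3 without). Late sporulation transcripts made up 7.96% ± 1.23 of the counts with calcium and 0.102% ± 0.0363 without (SD), and PerR transcripts 0.353% ± 0.0788 and 7.02% ± 0.388. Of 4190 genes, 1450 were called, 809 higher and 641 lower with calcium, 774 and 532 by at least 2-fold. Higher and lower calls were 645 and 385 without calcium replicate 1, 640 and 413 without the 4 shallowest libraries, 700 and 416 with library sizes only and 655 and 405 in a fit of the compared groups alone. The yhjR and sspO genes, without a count in the calcium-free libraries, were at least 40.0-fold and at least 34.6-fold higher. Lowest were katA (-5.64 ± 0.71, adjusted p = 2.2e-06) and sacP (-5.46 ± 0.80, adjusted p = 1.6e-05), the latter a sucrose uptake gene. Late sporulation had 42 higher, 0 lower and 0 not called (median 6.00, camera adjusted p = 6.2e-37, 0.0088 with estimated correlation) and a median of 5.95 with its zero-count member at the bound, and spoVFB was at 7.73 ± 0.40. Early sporulation had 23 higher, 0 lower and 2 not called (median 3.45, camera adjusted p = 1.2e-13, 0.034 with estimated correlation), with a median of 3.29 at the bound and safA (4.81 ± 0.35). Matrix genes had 18 higher, 0 lower and 1 not called (median 1.77, camera adjusted p = 2.4e-05, 0.36 with estimated correlation). Of these, tapA stood at 3.32 ± 0.42. Cannibalism genes had 9 higher, 0 lower and 2 not called (median 1.61, camera adjusted p = 0.0075, 0.47 with estimated correlation). Of these, skfB stood at 2.96 ± 0.38. The matrix genes tasA and epsA stood at 2.61 ± 0.53, adjusted p = 6.3e-04 and 2.35 ± 0.53, adjusted p = 0.0017. PerR genes had 0 higher, 13 lower and 0 not called (median -2.49, camera adjusted p = 2.3e-09, 0.078 with estimated correlation). Flagellar genes had 0 higher, 29 lower and 10 not called (median -1.22, camera adjusted p = 2.2e-07, 0.47 with estimated correlation). Of these, flgK stood at -1.66 ± 0.30. Iron uptake had 0 higher, 14 lower and 17 not called (median -1.02, camera adjusted p = 3.9e-05, 0.76 with estimated correlation). Of these, fhuD stood at -2.58 ± 0.38. Gluconeogenesis and glycolysis had 0 higher, 7 lower and 7 not called (median -1.03, camera adjusted p = 0.0075, 0.76 with estimated correlation). Of these, pckA stood at -2.05 ± 0.40. The SOS and prophage list was not called at day 1, with 6 higher, 0 lower and 26 not called (median 0.90, camera adjusted p = 0.66). The highest adjusted p of these list members was 4.2e-04 for pckA. Adjusted over the list alone, these lists kept their counts except biofilm matrix (19 higher and 0 lower), flagella (0 higher and 32 lower) and gluconeogenesis and glycolysis (0 higher and 8 lower).

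By day 2 (n = 3 each) the late sporulation share was 12% ± 2.34 with calcium and 0.135% ± 0.0432 without, and the PerR share 0.276% ± 0.0731 and 9.38% ± 0.991. Calcium changed 1687 genes, 926 higher and 761 lower, 865 and 583 by at least 2-fold. Lower calls outnumbered higher ones with upper quartile factors (861 and 895), the stricter filter (854 and 880), halved counts (876 and 936) and without no calcium replicate 2 (803 and 812). The named extremes with a symbol were ypzD (9.07 ± 1.12, adjusted p = 1.5e-06) and yczN (8.97 ± 0.82, adjusted p = 2.3e-08) above and katA (-6.54 ± 0.61, adjusted p = 3.6e-08) and mrgA (-6.07 ± 0.76, adjusted p = 1.8e-06) below. Late sporulation had 42 higher, 0 lower and 0 not called (median 5.91, camera adjusted p = 5.5e-34, 0.0093 with estimated correlation), with spoVFB at 6.42 ± 0.35. Early sporulation had 23 higher, 0 lower and 2 not called (median 3.44, camera adjusted p = 2.1e-11, 0.048 with estimated correlation), with a median of 3.38 at the bound and safA (4.25 ± 0.33). Matrix genes had 19 higher, 0 lower and 0 not called (median 2.45, camera adjusted p = 2.3e-07, 0.20 with estimated correlation). Of these, epsB stood at 3.25 ± 0.31. The matrix genes tasA and epsA stood at 3.27 ± 0.52, adjusted p = 3.3e-05 and 3.01 ± 0.52, adjusted p = 7.9e-05. Cannibalism genes had 10 higher, 0 lower and 1 not called (median 1.98, camera adjusted p = 0.011, 0.54 with estimated correlation). Of these, skfB stood at 2.84 ± 0.36. Arginine synthesis genes had 7 higher, 0 lower and 2 not called (median 1.63, camera adjusted p = 0.011, 0.79 with estimated correlation). Of these, argF stood at 1.63 ± 0.24. Genes of PerR had 0 higher, 13 lower and 0 not called (median -2.67, camera adjusted p = 2.3e-12, 0.048 with estimated correlation). Flagella had 0 higher, 33 lower and 6 not called (median -1.36, camera adjusted p = 2.9e-08, 0.43 with estimated correlation). Of these, flgK stood at -1.92 ± 0.27. SOS and prophage genes had 0 higher, 11 lower and 21 not called (median -1.12, camera adjusted p = 0.0012, 0.79 with estimated correlation). Of these, recA stood at -2.02 ± 0.26. The TCA cycle had 0 higher, 5 lower and 9 not called (median -0.55, camera adjusted p = 0.049, 0.79 with estimated correlation). Of these, sdhB stood at -1.82 ± 0.25. Gluconeogenesis and glycolysis had 0 higher, 7 lower and 7 not called (median -0.97, camera adjusted p = 0.022, 0.79 with estimated correlation). Of these, gapB stood at -1.30 ± 0.28. Among these list members the highest adjusted p was 7.6e-04 for gapB. The counts adjusted over the list alone were the same except in flagella (0 higher and 36 lower), gluconeogenesis and glycolysis (0 higher and 9 lower), SOS and PBSX prophage (0 higher and 8 lower) and arginine synthesis (8 higher and 0 lower).

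At day 3 (n = 3 with calcium, 2 without) mrgA was at 51.4 ± 17.7 CPM with calcium and 10102 ± 1655 without (SD; log2 fold change -7.61 ± 0.83, adjusted p = 1.5e-06). The late sporulation share was 12% ± 1.81 with calcium and 0.497% ± 0.0300 without. Calcium changed 1588 genes, 896 higher and 692 lower, 853 and 558 by at least 2-fold, and library sizes only gave 652 higher and 799 lower. Without no calcium replicate 1 or 3 the higher and lower calls were 556 and 548 or 625 and 451. They were 800 and 821 with the stricter filter, 850 and 878 with halved counts and 811 and 817 without calcium replicate 3. Highest were cotC (8.14 ± 1.69, adjusted p = 7.6e-04) and sspJ (7.89 ± 1.69, adjusted p = 0.0010), and katA (-6.49 ± 0.63, adjusted p = 5.0e-07) followed mrgA at the low end. Late sporulation had 41 higher, 0 lower and 1 not called (median 3.96, camera adjusted p = 2.7e-24, 0.029 with estimated correlation), with spoVFB at 4.0 ± 0.37, and early sporulation 20 higher, 0 lower and 5 not called (median 2.35, camera adjusted p = 4.6e-08, 0.12 with estimated correlation). Of these, safA stood at 2.83 ± 0.37. Matrix genes had 18 higher, 0 lower and 1 not called (median 2.25, camera adjusted p = 7.8e-08, 0.12 with estimated correlation). Of these, epsB stood at 3.05 ± 0.36. The matrix genes tasA and epsA stood at 3.42 ± 0.62, adjusted p = 2.2e-04 and 2.44 ± 0.58, adjusted p = 0.0025. The call of epsA was lost without no calcium day 3 replicate 1 (adjusted p = 0.060). Cannibalism genes had 10 higher, 0 lower and 1 not called (median 1.88, camera adjusted p = 0.0074, 0.44 with estimated correlation). Of these, sdpB stood at 2.61 ± 0.59. Arginine synthesis had 7 higher, 0 lower and 2 not called (median 1.66, camera adjusted p = 0.0015, 0.57 with estimated correlation). Of these, argC stood at 2.70 ± 0.40. Phosphate starvation had 12 higher, 1 lower and 6 not called (median 1.54, camera adjusted p = 0.0079, 0.69 with estimated correlation). Of these, tuaH stood at 1.65 ± 0.33. PerR genes fell, 0 higher, 12 lower and 1 not called (median -2.70, camera adjusted p = 7.9e-15, 0.029 with estimated correlation). SOS and prophage genes had 0 higher, 30 lower and 2 not called (median -2.80, camera adjusted p = 9.5e-16, 0.097 with estimated correlation). Of these, uvrA stood at -2.99 ± 0.33. Flagella had 0 higher, 26 lower and 13 not called (median -1.35, camera adjusted p = 3.0e-09, 0.28 with estimated correlation). Of these, motB stood at -1.66 ± 0.27. Iron uptake had 0 higher, 10 lower and 21 not called (median -0.22, camera adjusted p = 0.033, 0.69 with estimated correlation). Of these, efeN stood at -2.58 ± 0.41. The TCA cycle had 0 higher, 4 lower and 10 not called (median -0.60, camera adjusted p = 0.014, 0.57 with estimated correlation). Of these, sdhB stood at -2.05 ± 0.27. Gluconeogenesis and glycolysis had 0 higher, 6 lower and 8 not called (median -0.93, camera adjusted p = 0.018, 0.60 with estimated correlation). Of these, fbp stood at -1.59 ± 0.32. General stress genes had 0 higher, 8 lower and 16 not called (median -1.78, camera adjusted p = 0.012, 0.69 with estimated correlation). Of these, csbC stood at -3.50 ± 0.99. Its share was 1.60 and 5.11% in calcium-free replicates 1 and 3, more than 3-fold apart, and 0.985% ± 0.233 with calcium. The members named here had adjusted p of up to 0.0085 for csbC. Medians with library sizes only were -0.59 for iron uptake and -0.93 for the TCA cycle. The call of csbC was lost without no calcium day 3 replicate 3 (adjusted p = 0.20). Counts adjusted over the list alone differed for biofilm matrix (19 higher and 0 lower), flagella (0 higher and 28 lower), early sporulation (22 higher and 0 lower), late sporulation (42 higher and 0 lower), TCA cycle (0 higher and 3 lower), phosphate starvation (14 higher and 1 lower), general stress (0 higher and 1 lower), peroxide stress (0 higher and 13 lower) and arginine synthesis (8 higher and 0 lower).

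At day 6 (n = 3 each) ahpC was still lower with calcium, 431 ± 304 CPM against 4339 ± 648 (SD; log2 fold change -3.33 ± 0.46, adjusted p = 2.0e-04), whereas the late sporulation share was 13.7% ± 2.65 with calcium and 8.07% ± 0.750 without. Calcium changed 473 genes, 155 higher and 318 lower, 136 and 264 by at least 2-fold. The split of higher against lower calls moved with the scaling, to 245 and 252 with DESeq2 size factors, 378 and 325 with DESeq2, and 61 and 632 with library sizes only. Leaving out a library also moved it, to 47 and 165 (212 calls) without no calcium replicate 1, 74 and 235 (309) without no calcium replicate 3, 81 and 230 (311) without calcium replicate 1 and 56 and 171 (227) without calcium replicate 2. It was 50 and 223 (273) without the 4 shallowest libraries and 79 and 112 (191) in a fit of the compared groups alone. With the number in the titles as a block there were 764 calls, 313 and 451. The block changed no list call and brought tasA past the threshold (1.51, adjusted p = 0.0045). The extremes were ykoJ (4.18 ± 0.75, adjusted p = 0.0018) and yhdB (3.89 ± 0.93, adjusted p = 0.011) above and mrgA (-4.65 ± 0.71, adjusted p = 4.4e-04) and yrkF (-4.23 ± 1.04, adjusted p = 0.013) below. PerR genes had 0 higher, 13 lower and 0 not called (median -1.91, camera adjusted p = 3.6e-19, 0.012 with estimated correlation). SOS and prophage genes had 0 higher, 17 lower and 15 not called (median -2.33, camera adjusted p = 4.1e-15, 0.15 with estimated correlation), with a median of -2.20 at the bound and dinB (-2.93 ± 0.37), and flagella 1 higher, 24 lower and 14 not called (median -1.25, camera adjusted p = 3.6e-13, 0.29 with estimated correlation). Of these, fliL stood at -2.54 ± 0.39. Matrix genes had 3 higher, 0 lower and 16 not called (median 1.08, camera adjusted p = 1.1e-05, 0.29 with estimated correlation). Of these, tapA stood at 2.52 ± 0.39. The matrix genes tasA and epsA stood at 1.35 ± 0.48, adjusted p = 0.074 and 1.08 ± 0.49, adjusted p = 0.16. The gene tasA passed the threshold without no calcium day 6 replicate 2 (adjusted p = 0.027) and with DESeq2 (adjusted p = 0.015). The call of yhdB was lost without no calcium day 6 replicate 1 (adjusted p = 0.055) and without calcium day 6 replicate 2 (adjusted p = 0.057). The call of yrkF was lost without calcium day 6 replicate 2 (adjusted p = 0.052).

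Also at day 6, late sporulation had 2 higher, 0 lower and 40 not called (median 0.54, camera adjusted p = 3.5e-04, 0.54 with estimated correlation), and this median was -0.03 with library sizes only. Early sporulation had 0 higher, 0 lower and 25 not called (median 0.43, camera adjusted p = 0.0096, 0.54 with estimated correlation), a median that library sizes only turned to -0.12. Sulfur and cysteine had 2 higher, 0 lower and 24 not called (median 0.38, camera adjusted p = 0.019, 0.54 with estimated correlation), -0.20 with library sizes only. Divalent cation transport had 0 higher, 6 lower and 9 not called (median -0.13, camera adjusted p = 0.025, 0.54 with estimated correlation), a median of 0.00061 with DESeq2 size factors, and mntB (-1.85 ± 0.31). Phosphate starvation had 3 higher, 0 lower and 16 not called (median 0.69, camera adjusted p = 0.0019, 0.54 with estimated correlation). The TCA cycle had 0 higher, 3 lower and 11 not called (median -0.45, camera adjusted p = 0.036, 0.54 with estimated correlation). Gluconeogenesis and glycolysis had 0 higher, 1 lower and 13 not called (median -0.57, camera adjusted p = 0.047, 0.54 with estimated correlation). Arginine synthesis had 0 higher, 0 lower and 9 not called (median -0.77, camera adjusted p = 0.014, 0.54 with estimated correlation). Branched-chain amino acid synthesis had 0 higher, 3 lower and 7 not called (median -0.61, camera adjusted p = 0.0073, 0.54 with estimated correlation). Calcium-free replicate 1 stood above replicates 2 and 3 in the shares of phosphate starvation (0.209, 0.0952 and 0.0688%), arginine synthesis (0.428, 0.154 and 0.194%) and sulfur and cysteine (1.00, 0.363 and 0.445%). Other day 6 medians with library sizes only were 0.09 for phosphate starvation, 0.54 for biofilm matrix, -0.57 for divalent cation transport, -1.02 for the TCA cycle, -1.08 for gluconeogenesis and glycolysis, -1.32 for arginine synthesis and -1.17 for branched-chain amino acid synthesis. Adjusted over the list alone, the day 6 counts differed for biofilm matrix (9 higher and 0 lower), flagella (1 higher and 30 lower), gluconeogenesis and glycolysis (0 higher and 0 lower), phosphate starvation (4 higher and 0 lower), SOS and PBSX prophage (0 higher and 23 lower), arginine synthesis (0 higher and 8 lower), branched-chain amino acid synthesis (0 higher and 4 lower) and sulfur and cysteine (1 higher and 0 lower).

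Whether the effect of calcium differed between days was tested with 3 contrasts at once, and 530 of 4190 genes differed. The 5 genes of lowest p were spoVFB, yfnG, aprX, spsB and spsJ, of which spsB and spsJ belong to a spore surface polysaccharide operon. Their log2 effect at day 6 minus that at day 1 was -7.40 for spoVFB (adjusted p = 1.5e-08), -6.02 for yfnG (adjusted p = 1.6e-08), -5.84 for aprX (adjusted p = 2.7e-08), -5.11 for spsB (adjusted p = 3.5e-08) and -5.28 for spsJ (adjusted p = 3.5e-08). In the libraries themselves, spoVFB rose without calcium from 1.45 ± 0.164 CPM at day 1 to 386 ± 42.3 at day 6 and with calcium stood at 321 ± 155 and 485 ± 156 (SD, n = 3, 3, 2 and 3). Called at all 4 days were 102 genes higher and 196 lower, and at days 1, 2 and 3 together 617 higher and 395 lower. Days 1 and 2 shared 695 genes called higher, where independent lists would share 178.8, and their log2 fold changes correlated across genes at Spearman 0.843. For days 1 and 6 these values were 108, 29.9 and 0.612. Genes are not independent replicates, and no library was shared between days.

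**Figure D2:**
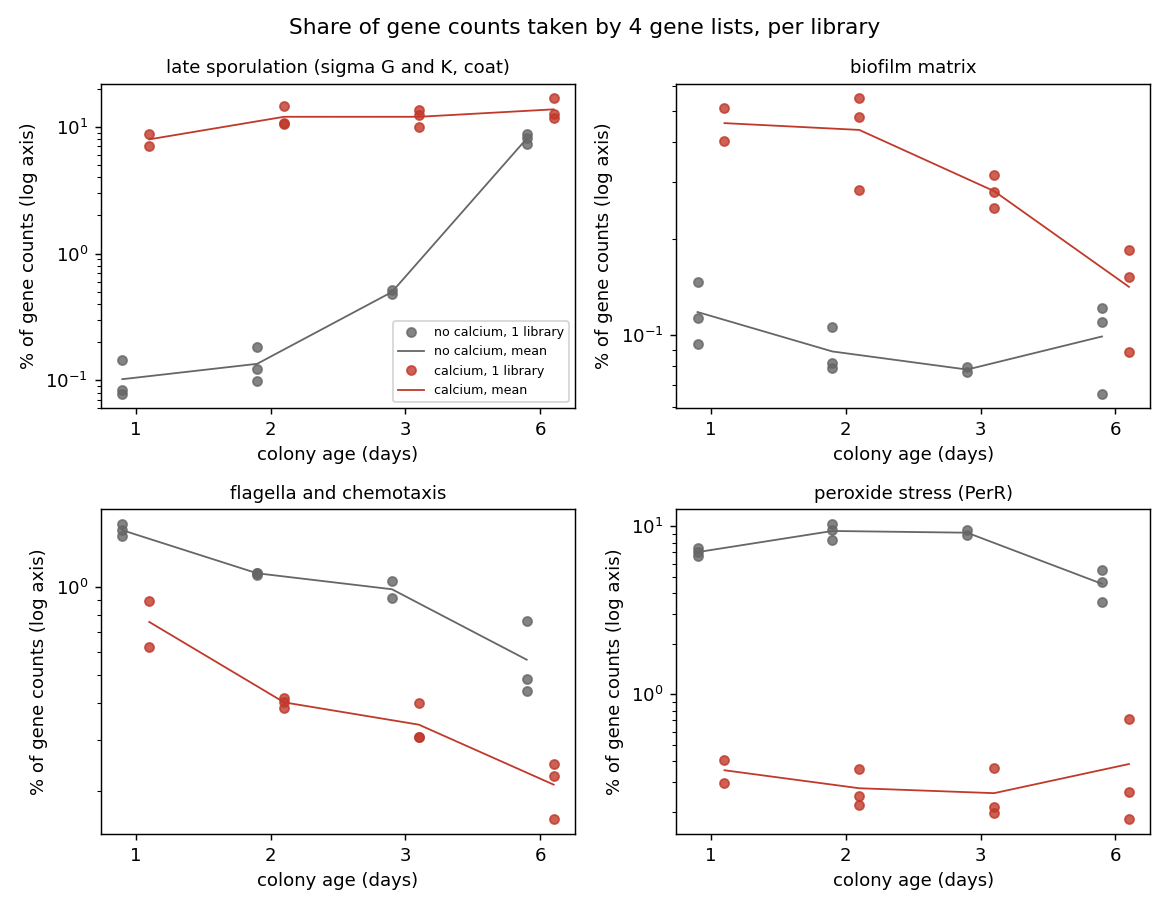
Share of gene counts, in percent on a log axis, taken by the late sporulation, biofilm matrix, flagella and PerR lists against colony age in days, one point per library, lines through group means, calcium in red and no calcium in grey. Without calcium the late sporulation share went from 0.102% at day 1 to 8.07% at day 6, and with calcium from 7.96% to 13.7%.

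Colony age was examined within each medium as day 6 against day 1. Without calcium (n = 3 each) older colonies carried more sporulation transcripts and fewer of phosphate starvation: spoVFB rose by 8.0 ± 0.39 on the log2 scale and tuaG, of the teichuronic acid operon, changed by -3.52 ± 0.33. Of 4190 genes, 1306 changed, 816 higher and 490 lower at day 6, 756 and 312 by at least 2-fold. Without no calcium day 6 replicate 2 the calls were 734 and 297, and without replicate 1 745 and 699. Absent from the day 1 counts, yhjR and yuzL were at least 41.5-fold and at least 27.1-fold higher, and the lowest were tatAD (-5.58 ± 0.71, adjusted p = 2.5e-06) and phoD (-4.97 ± 0.67, adjusted p = 4.9e-06), a phosphodiesterase gene phoD and its export gene. Late sporulation had 42 higher, 0 lower and 0 not called (median 6.09, camera adjusted p = 1.9e-39, 0.0051 with estimated correlation, 5.95 at the bound). Early sporulation had 22 higher, 0 lower and 3 not called (median 3.30, camera adjusted p = 2.2e-14, 0.023 with estimated correlation, 3.15 at the bound). Phosphate starvation had 0 higher, 16 lower and 3 not called (median -3.31, camera adjusted p = 2.4e-13, 0.18 with estimated correlation). Surfactin and other products had 1 higher, 31 lower and 5 not called (median -1.44, camera adjusted p = 6.5e-10, 0.36 with estimated correlation). Of these, bacD stood at -2.25 ± 0.34. Flagella had 0 higher, 34 lower and 5 not called (median -1.48, camera adjusted p = 3.9e-12, 0.18 with estimated correlation). Of these, fliG stood at -1.69 ± 0.27. Anaerobic and low oxygen genes had 1 higher, 15 lower and 7 not called (median -1.11, camera adjusted p = 2.4e-05, 0.61 with estimated correlation). Of these, ldh stood at -2.65 ± 0.41. The TCA cycle had 0 higher, 7 lower and 7 not called (median -0.76, camera adjusted p = 0.014, 0.66 with estimated correlation). Of these, sucD stood at -1.44 ± 0.26. Gluconeogenesis and glycolysis had 0 higher, 9 lower and 5 not called (median -0.90, camera adjusted p = 0.0053, 0.62 with estimated correlation). Of these, pgm stood at -1.95 ± 0.35. Polyglutamate synthesis had 0 higher, 4 lower and 2 not called (median -1.46, camera adjusted p = 0.0098, 0.21 with estimated correlation). Of these, capA stood at -4.46 ± 0.61. Ribosomal proteins had 0 higher, 6 lower and 41 not called (median -0.48, camera adjusted p = 0.012, 0.81 with estimated correlation). Of these, rpsNA stood at -1.11 ± 0.29. Iron uptake had 0 higher, 3 lower and 28 not called (median -0.39, camera adjusted p = 0.036, 0.80 with estimated correlation). The named list members had adjusted p of up to 0.0052 for rpsNA. Library sizes only gave medians of -0.79 for iron uptake and -0.79 for ribosomal proteins. Over the list alone, the adjusted counts differed for flagella (0 higher and 38 lower), early sporulation (23 higher and 0 lower), iron uptake (0 higher and 0 lower), anaerobic and low oxygen (1 higher and 17 lower), ribosomal proteins (0 higher and 1 lower) and surfactin and other products (1 higher and 33 lower).

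With calcium (n = 2 at day 1, 3 at day 6) genes of the phosphate starvation, pyrimidine and joint SOS and prophage lists fell with age. Examples were tuaB (-3.12 ± 0.37), pyrD (-5.94 ± 1.10) and the SOS gene dinB (-3.32 ± 0.40). Age changed 471 genes, 201 higher and 270 lower, 184 and 252 by at least 2-fold. Leaving out calcium day 1 replicate 1 gave 275 (41 and 234) and leaving out replicate 2 230 (66 and 164), higher before lower. The 4 shallowest libraries left out gave 193 (44 and 149), and a fit of the compared groups alone 279 (92 and 187). With DESeq2 the split was 332 and 329, and with the number in the titles as a block 387 and 400 (787 calls). Library sizes only gave 737 calls, 24 higher and 713 lower, and upper quartile factors 163 higher and 318 lower. The extremes were ypzF (4.12 ± 1.01, adjusted p = 0.012) and uxaC (3.84 ± 0.74, adjusted p = 0.0024) above and pyrD (-5.94 ± 1.10, adjusted p = 0.0019) and pyrF (-5.72 ± 1.47, adjusted p = 0.014) below, both pyrimidine synthesis genes. Phosphate starvation had 0 higher, 16 lower and 3 not called (median -2.87, camera adjusted p = 1.5e-21, 0.059 with estimated correlation). SOS and prophage genes had 0 higher, 22 lower and 10 not called (median -3.0, camera adjusted p = 1.5e-21, 0.045 with estimated correlation, -2.91 at the bound). Surfactin and other products had 0 higher, 26 lower and 11 not called (median -1.51, camera adjusted p = 8.2e-19, 0.075 with estimated correlation). Of these, pksM stood at -1.52 ± 0.26. Flagella had 0 higher, 24 lower and 15 not called (median -1.48, camera adjusted p = 6.3e-18, 0.075 with estimated correlation). Of these, fliL stood at -3.14 ± 0.41. Anaerobic and low oxygen genes had 0 higher, 8 lower and 15 not called (median -0.98, camera adjusted p = 3.5e-10, 0.14 with estimated correlation). Of these, ldh stood at -3.43 ± 0.45. Pyrimidine genes had 0 higher, 9 lower and 2 not called (median -3.60, camera adjusted p = 3.7e-07, 0.11 with estimated correlation). Polyglutamate genes had 0 higher, 4 lower and 2 not called (median -2.05, camera adjusted p = 2.4e-06, 0.038 with estimated correlation). Of these, capA stood at -5.24 ± 0.68. Matrix genes had 0 higher, 4 lower and 15 not called (median -0.93, camera adjusted p = 4.2e-05, 0.18 with estimated correlation). Of these, epsJ stood at -1.68 ± 0.34. Divalent cation transport had 5 higher, 0 lower and 10 not called (median 1.02, camera adjusted p = 0.0019, 0.15 with estimated correlation). Of these, mntC stood at 2.02 ± 0.36. Adjusted p of the list members was at most 0.0036 for epsJ. The call of ypzF was lost without calcium day 1 replicate 1 (adjusted p = 0.13), without calcium day 1 replicate 2 (adjusted p = 0.054) and without the 4 shallowest libraries (adjusted p = 0.16). The call of uxaC was lost without the 4 shallowest libraries (adjusted p = 0.096). The call of pyrF was lost without calcium day 1 replicate 2 (adjusted p = 0.083), without calcium day 6 replicate 3 (adjusted p = 0.062) and without calcium day 6 replicate 2 (adjusted p = 0.065). The call of mntC was lost with library sizes only (adjusted p = 0.059).

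Other lists were also called with age on calcium. Arginine and ornithine degradation had 0 higher, 4 lower and 3 not called (median -1.33, camera adjusted p = 8.4e-05, 0.11 with estimated correlation). The TCA cycle had 0 higher, 3 lower and 11 not called (median -0.65, camera adjusted p = 0.0018, 0.30 with estimated correlation). Ribosomal proteins had 0 higher, 9 lower and 38 not called (median -0.61, camera adjusted p = 0.0018, 0.68 with estimated correlation). Cell envelope stress had 1 higher, 3 lower and 20 not called (median -0.69, camera adjusted p = 0.0027, 0.20 with estimated correlation). Urease and nitrogen had 0 higher, 2 lower and 17 not called (median -0.64, camera adjusted p = 0.0062, 0.35 with estimated correlation). Purine synthesis had 0 higher, 1 lower and 18 not called (median -0.81, camera adjusted p = 0.0018, 0.40 with estimated correlation). Pointing up were sulfur and cysteine, 6 higher, 0 lower and 20 not called (median 0.71, camera adjusted p = 2.5e-04, 0.25 with estimated correlation), with a median of -0.08 under library sizes only, and late sporulation, 1 higher, 0 lower and 41 not called (median 0.84, camera adjusted p = 2.5e-04, 0.37 with estimated correlation), with -0.10. Early sporulation had 0 higher, 0 lower and 25 not called (median 0.48, camera adjusted p = 0.032, 0.49 with estimated correlation) and -0.32 under library sizes only. Fatty acid degradation had 1 higher, 0 lower and 10 not called (median 0.52, camera adjusted p = 0.012, 0.49 with estimated correlation). Iron uptake had 3 higher, 0 lower and 28 not called (median 0.41, camera adjusted p = 0.040, 0.74 with estimated correlation), and library sizes only gave them -0.23 and -0.29. The other medians that library sizes only moved by over 1.5 times were 0.26 for divalent cation transport, -1.71 for biofilm matrix, -1.71 for anaerobic and low oxygen, -2.09 for arginine and ornithine degradation, -1.38 for the TCA cycle, -1.39 for ribosomal proteins, -1.46 for cell envelope stress, -1.37 for urease and nitrogen and -1.54 for purine synthesis. Adjusted over the list alone, the counts of the lists called on calcium differed for biofilm matrix (0 higher and 8 lower), flagella (0 higher and 30 lower), late sporulation (0 higher and 0 lower), calcium and other divalent cation transport (7 higher and 1 lower), TCA cycle (0 higher and 5 lower), anaerobic and low oxygen (0 higher and 13 lower), cell envelope stress (1 higher and 4 lower), SOS and PBSX prophage (0 higher and 25 lower), ribosomal proteins (0 higher and 15 lower), purine synthesis (0 higher and 0 lower), pyrimidine synthesis (1 higher and 9 lower), arginine and ornithine degradation (0 higher and 5 lower), surfactin and other products (0 higher and 30 lower), polyglutamate synthesis (0 higher and 6 lower) and sulfur and cysteine (9 higher and 0 lower).

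The cueR comparison asked what loss of cueR changes at day 3 on calcium (n = 3 each). The gene itself had 37, 18 and 25 counts in deletion replicates 1, 3 and 4 (21.8, 20.8 and 18.5 CPM) and 79, 418 and 283 counts in wild-type replicates 1, 2 and 3 (87.1, 137 and 149 CPM), lower in 3 of 3 deletion libraries but not at 0 (log2 fold change -2.61 ± 0.28, adjusted p = 0.0020). Copper transporter gene copA was at 68.4 ± 4.23 CPM in the deletion and 28.8 ± 1.01 in the wild type (SD; log2 fold change 1.24 ± 0.21, adjusted p = 0.0090). The copper chaperone gene copZ (0.50 ± 0.28, adjusted p = 0.28) and the copper repressor gene csoR (0.96 ± 0.35, adjusted p = 0.12) were not called. The call of copA was lost without wild type replicate 3 (adjusted p = 0.057). The gene csoR passed the threshold without deletion replicate 4 (adjusted p = 0.011). Of 3759 genes, 594 changed, 414 higher and 180 lower in the deletion, 381 and 159 by at least 2-fold. With library sizes only the split was 284 higher and 247 lower. Leaving out deletion replicate 4 gave 1287 (685 and 602) calls, and leaving out wild-type replicate 1, 2 or 3 gave 306 (206 and 100), 218 (146 and 72) and 222 (142 and 80), higher before lower. Outside the rule for named genes, yhdP, also called mpfA and next to cueR, was picked after its values were seen, with 3972, 1990 and 3329 counts in the deletion and 164, 525 and 303 in the wild type (log2 fold change 3.79 ± 0.19, adjusted p = 6.0e-04).

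Highest among the called genes with a mean of at least 10 CPM were comGB and comGA of the DNA uptake machinery (6.61 ± 1.02, adjusted p = 0.0072 and 4.83 ± 0.61, adjusted p = 0.0040) and the surfactin synthetase genes srfAC (4.84 ± 0.31, adjusted p = 6.0e-04), srfAA (4.70 ± 0.35, adjusted p = 7.4e-04) and srfAB (4.61 ± 0.36, adjusted p = 7.6e-04). Lowest were yfmS (-5.65 ± 0.36, adjusted p = 6.0e-04), ylxF (-5.44 ± 0.85, adjusted p = 0.0076), yjfB (-5.28 ± 0.63, adjusted p = 0.0029), cheC (-4.65 ± 0.69, adjusted p = 0.0066) and hag, the flagellin gene (-4.61 ± 0.33, adjusted p = 6.2e-04). Matrix genes rose, 19 higher, 0 lower and 0 not called (median 2.69, camera adjusted p = 5.6e-29, 0.15 with estimated correlation), with sipW (3.85 ± 0.25) and tasA (3.73 ± 0.30). Flagella and chemotaxis fell, 0 higher, 28 lower and 8 not called (median -2.92, camera adjusted p = 1.9e-39, 0.15 with estimated correlation), with a median of -2.85 at the bound, where fliJ had no counts in the deletion and was at least 6.61-fold lower. General stress genes had 23 higher, 0 lower and 1 not called (median 1.47, camera adjusted p = 4.9e-16, 0.44 with estimated correlation). Of these, ydaD stood at 3.41 ± 0.31. Cannibalism genes had 8 higher, 0 lower and 3 not called (median 2.22, camera adjusted p = 5.6e-13, 0.40 with estimated correlation). Of these, skfA stood at 4.07 ± 0.29. Early sporulation had 21 higher, 0 lower and 3 not called (median 2.17, camera adjusted p = 1.2e-14, 0.49 with estimated correlation). Of these, spoIIIAF stood at 2.12 ± 0.25. Its share of counts was 1.08, 0.942 and 2.91% in deletion replicates 1, 3 and 4, and 0.420% ± 0.000554 in the wild type. Late sporulation had 4 higher, 1 lower and 36 not called (median 0.67, camera adjusted p = 0.90), and its share was 1.03, 0.888 and 6.65% in the same deletion libraries and 3.24% ± 0.291 in the wild type. Competence had 5 higher, 0 lower and 6 not called (median 0.50, camera adjusted p = 0.0016, 0.45 with estimated correlation). Osmoprotectants had 6 higher, 0 lower and 15 not called (median 0.68, camera adjusted p = 0.017, 0.70 with estimated correlation). Arginine synthesis had 1 higher, 0 lower and 8 not called (median 1.23, camera adjusted p = 0.017, 0.70 with estimated correlation). With library sizes only the medians were 0.26 for competence and 0.41 for osmoprotectants. Surfactin and other products had 4 higher, 0 lower and 33 not called (median -0.06, camera adjusted p = 0.25). Polyglutamate genes had 0 higher, 3 lower and 2 not called (median -1.28, camera adjusted p = 0.0011, 0.36 with estimated correlation). Of these, pgdS stood at -3.33 ± 0.29. Anaerobic and low oxygen genes had 0 higher, 8 lower and 15 not called (median -0.65, camera adjusted p = 2.2e-04, 0.49 with estimated correlation). Of these, lctP stood at -1.77 ± 0.29. Fatty acid degradation had 0 higher, 2 lower and 9 not called (median -0.78, camera adjusted p = 0.0096, 0.62 with estimated correlation). PerR had 0 higher, 2 lower and 11 not called (median -0.53, camera adjusted p = 0.015, 0.70 with estimated correlation). The PerR share was 1.74, 1.84 and 0.506% in deletion replicates 1, 3 and 4, and 2.92% ± 0.0883 in the wild type. SOS and prophage genes had 1 higher, 2 lower and 19 not called (median -1.02, camera adjusted p = 0.018, 0.70 with estimated correlation). Arginine and ornithine degradation had 0 higher, 2 lower and 5 not called (median -0.57, camera adjusted p = 0.021, 0.48 with estimated correlation). Copper genes had 2 higher, 1 lower and 6 not called (camera adjusted p = 0.76), with copB at 1.47 ± 0.35, adjusted p = 0.031 beside copA and cueR. The list members given without p had adjusted p of up to 0.0083 for lctP. The call of copB was lost without deletion replicate 1 (adjusted p = 0.071), without wild type replicate 1 (adjusted p = 0.080), without wild type replicate 2 (adjusted p = 0.093), without wild type replicate 3 (adjusted p = 0.10) and with library sizes only (adjusted p = 0.11). No list call in the cueR comparison held with an estimated correlation. Over the list alone the adjusted counts differed for flagella (0 higher and 31 lower), early sporulation (24 higher and 0 lower), fatty acid degradation (0 higher and 4 lower), anaerobic and low oxygen (0 higher and 9 lower), arginine synthesis (6 higher and 0 lower), arginine and ornithine degradation (0 higher and 3 lower) and cannibalism (11 higher and 0 lower).

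**Figure D3:**
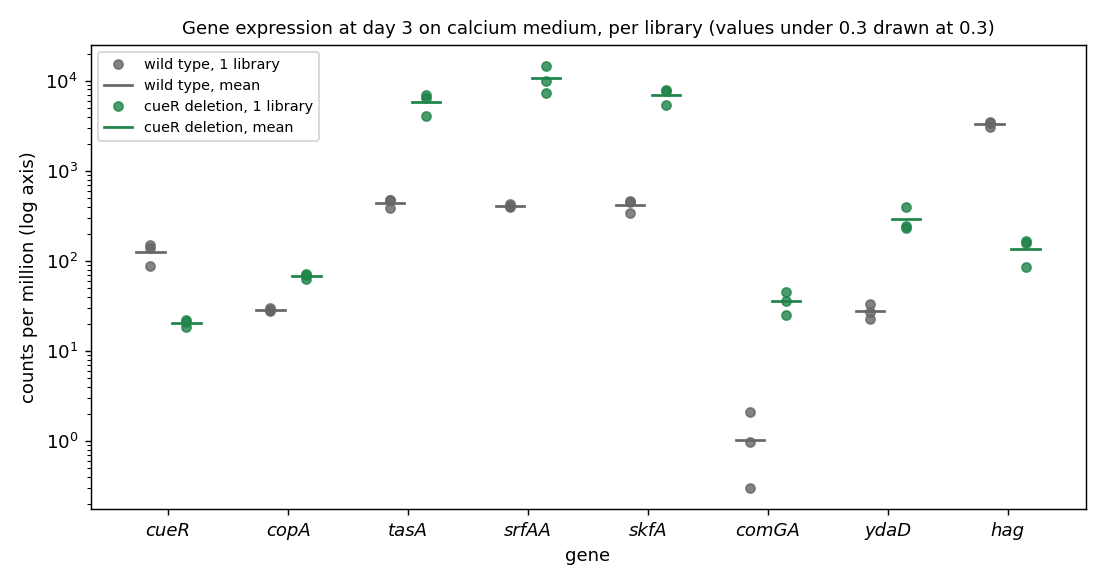
CPM on a log axis of cueR, copA, tasA, srfAA, skfA, comGA, ydaD and hag in each library of the cueR table, wild type in grey and deletion in green, short lines at group means, values under 0.3 CPM drawn at 0.3. The cueR points lie at 21.8, 20.8 and 18.5 CPM in the deletion and 87.1, 137 and 149 CPM in the wild type.

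Log2 fold changes for calcium at day 3 and for the deletion, from tables sharing no library, were compared over 3657 genes tested in both. They correlated across genes at Spearman 0.262 and Pearson 0.225. Genes higher in both numbered 183, against 92.6 for independent lists (2-sided Fisher's exact p = 3.7e-26, adjusted 2.9e-25). Genes lower in both numbered 63, against 32.3 (exact p = 2.0e-08, adjusted 4.0e-08). Higher in the deletion and lower with calcium were 64, against 73.7 (exact p = 0.20, adjusted 0.20), and lower in the deletion but higher with calcium 18, against 40.5 (exact p = 1.3e-05, adjusted 1.5e-05). With the calcium mean of 4 days in place of day 3, higher in both were 227, against 133 (exact p = 5.3e-24, adjusted 2.1e-23) and lower in both 94, against 59.4 (exact p = 5.3e-08, adjusted 8.5e-08). Higher in the deletion and lower with calcium were then 76, against 136 (exact p = 4.8e-12, adjusted 1.3e-11), and lower in the deletion but higher with calcium 29, against 58.4 (exact p = 4.8e-07, adjusted 6.4e-07). These tests treat genes as independent, which those of one operon are not. All keep deletion replicate 4. With the block, which drops it, late sporulation fell (median -2.68) where calcium raised it.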

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

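In this part, the tests of the phosphate starvation list, of both explanations for the cueR locus, of composition and of the cueR level in replicate 4 were chosen after the result was seen. A difference between days was found for 530 of 4190 genes (edgeR, 3 contrasts at once). For the named genes among them, the log2 effect of calcium at day 6 minus that at day 1 was spoVFB -7.40, yfnG -6.02, aprX -5.84, spsB -5.11, spsJ -5.28, katA 2.19, yosA -5.87, mrgA -1.16, yhbE 2.01, cgeB -7.09, cotA -4.96, safA -4.43, spoIVA -3.99, epsB -1.21, skfB -2.86, recA -1.01, uvrA -0.61, mntC 2.88, mntB 2.42, yloB -3.45, argC 0.00948 and ssuA -2.41. The highest adjusted p among these, over all 3 contrasts, was 0.020 for mrgA. For argC this difference was near 0, and the test also covers days 2 and 3.

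Late sporulation genes were higher with calcium at day 2, with a median log2 fold change of 5.91. Composition of the libraries, whose scaling moves all genes of a library alike, is argued against by a distance of 5.87 (SD of members 1.79) from the median of all other genes, and low depth by the median of 5.92 without the 4 shallowest libraries. A general shift of every gene along the time course was examined with the phosphate starvation list, which fell with age without calcium. Its median calcium effect was 0.19 (SD of members 0.91), so its genes did not show that fall. The list was higher with calcium at day 3, so an effect of calcium on these genes could hide a shift, and the list cannot decide. Open remain such a general shift and an expression of sporulation genes alone at an earlier colony age with calcium. The calcium effect at day 2 and the change from day 1 to day 6 without calcium correlated across genes at Spearman 0.605. The value was 0.586 without the early and late sporulation lists, which leaves in other spore genes such as sspJ and spsB. This correlation does not tell the explanations apart. Both are hypotheses, found and tested on the same data.

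At the cueR locus, deletion libraries kept 16.4% of the wild-type cueR level, and yhdP next to it was higher (3.79 ± 0.19). Wild-type RNA mixed into them would leave every gene at least that share, and 16 genes with a wild-type mean of 20 CPM or more kept less than 1/2 of it. A change of the whole region is argued against by a median log2 fold change of -0.17 over 6 tested genes among the 6 nearest on each side, of which yhdN was called (1.15 ± 0.19, adjusted p = 0.0090). The call of yhdN was lost without wild type replicate 3 (adjusted p = 0.052). Reads from a part of cueR left in place, or an effect of the construct on yhdP, stay open, since no read positions were analysed here, and no biological explanation was tested.

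In deletion replicate 4, late sporulation genes were higher than in replicates 1 and 3, with a median log2 ratio of 4.42. A wild-type library under a wrong label is argued against by its cueR level of 18.5 CPM, below 72.4, the middle of both genotypes. Composition is argued against by a distance of 4.44 (SD of members 1.69) from the median of all other genes. Open remains that this colony may be at a later stage of sporulation: its log2 ratio correlated with the change from day 1 to day 6 without calcium at Spearman 0.465 across 3657 genes.

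Data outside the comparisons held little signal. Of the 78 rows of the cueR table without a gene name, 1 had 27 counts over the deletion libraries, at least 3 in each, and none in the wild type, and 0 had the opposite pattern. The 26 rows left blank for days 1 to 3 had values at day 6, with a highest total of 16 counts.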

How the results depend on the processing

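Alternatives with halved counts, with library sizes only and without the 4 shallowest libraries together were tests chosen after the data were seen. Of 763 gene values named by the rule or chosen for the text, 739 were called, and 505 of these kept direction and call in every alternative run, while 234 lost the call in at least 1, 208 on leaving out a library and 92 under a scaling. None of the called values reversed. Calls kept throughout were 118 of 129 for the calcium mean, 61 of 89, 86 of 102, 73 of 104 and 27 of 67 at days 1, 2, 3 and 6, 67 of 96 and 25 of 72 with age without and with calcium, and 48 of 80 for cueR. Of 14508 alternatives for these values, 13600 kept call and direction, 857 lost the call, 21 gained one and 30 turned the sign, the last for uncalled lcfA, fadR and fadB values.

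Leaving out 1 library at a time gave 1030 to 1478 called genes at day 1, 1418 to 1673 at day 2, 1076 to 1628 at day 3, 212 to 509 at day 6, 2454 to 2714 in the mean, 485 to 551 for the difference between days, 1031 to 1466 and 230 to 446 with age without and with calcium, and 218 to 1287 for cueR. A lone library left in a group was assumed to vary like the other groups. The counts per library left out at day 6, with age on calcium and for cueR are given above. The number in the titles as a block gave 1587 genes at day 1, 764 at day 6 and 787 with age on calcium. It gave 1037 for cueR, 528 higher and 509 lower. The block drops deletion replicate 4 and wild-type replicate 2 from that contrast, as only numbers 1 and 3 are in both genotypes. It changed the named calls of tasA at day 6, csoR for cueR (adjusted p = 0.038), pyrK at day 1, comK, mcsB and leuB at day 3, rpmEB with age without calcium and xkdA for cueR, and the list calls of iron uptake at days 2 and 3, with age on calcium and for cueR. For cueR it ended those of PerR, SOS, both arginine lists and osmoprotectants and called surfactin and other products (camera adjusted p = 0.0014). It also called late sporulation lower (median -2.68 against 0.67 without the block). Of 20 libraries with a same-numbered partner, 19 correlated best with their own number. The groups compared alone gave 191 at day 6 and 279 with age on calcium, and are the full set for the calcium mean. Without the 4 shallowest libraries the counts were 273 at day 6 and 193 with age on calcium, with fewer libraries compared, and library sizes only gave 737 with age on calcium. A 2-fold minimum left 1500 genes in the mean, by construction. For the other changes the cause was not tested.

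Scaling moved the balance of directions. With library sizes only the median log2 fold change of all genes was -0.17, -0.26 and -0.54 at days 2, 3 and 6, -0.24 in the mean, -0.31 and -0.68 with age without and with calcium, and -0.26 for cueR, against 0.05, 0.10, -0.03, 0.05, 0.02, 0.10 and -0.02 with TMM. Upper quartile factors gave -0.07 at day 2 and -0.08 and -0.01 with age, and at day 6 DESeq2 size factors gave 0.10. Higher and lower calls with the stricter filter were 737 and 695 with age without calcium and 162 and 344 on calcium, and with halved counts 762 and 726 and 158 and 332, against 816 and 490 and 201 and 270.

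Signs of uncalled values turned as follows. For fadB at day 1, DESeq2 size factors gave 0.00753, DESeq2 0.00880, leaving out the 4 shallowest libraries 0.53 and leaving out single libraries -0.96 to 0.51. For lcfA at day 2, single libraries left out gave -0.0358 to 0.32. For fadR at day 2, upper quartile factors gave -0.0382, the stricter filter -9.7e-05, halved counts -0.0198, library sizes only -0.11 and single libraries left out -0.15 to 0.11. For lcfA at day 3 these values were -0.0193, -0.0391, -0.0591, -0.26 and -0.27 to 0.23, and the compared groups alone gave -0.0172. At day 6, library sizes only gave -0.33 for lcfA, -0.34 for fadR and -0.37 for fadB, and single libraries left out -0.0361 to 0.44 for fadR and -0.0666 to 0.38 for fadB. In the mean, library sizes only gave -0.0366 for lcfA and -0.17 for fadR, and fadB was 0.0149 without the 4 shallowest libraries.

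With an estimated correlation camera called 2 lists at day 1, 3 at day 2, 2 at day 3, 1 at day 6, 2 in the mean, 2 with age in each medium and 0 for cueR, against 8, 10, 13, 13, 10, 11, 20 and 14 with the preset one. The fry test called 23 lists in the mean. The correlation of the cueR and calcium responses, 0.262, was 0.288 over genes called in either, 0.321 with the calcium mean and 0.262 with DESeq2 values.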

Other observations

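The comparisons of colony shares and of cueR and yhdP across tables were chosen after the data were seen; the splits of libraries were planned. Wild-type colonies at day 3 on calcium are present in both tables, which were not tested against each other. Their late sporulation share was 12% in the larger table and 3.24% in the cueR table, the matrix share 0.282% and 0.157%, the flagella share 0.338% and 0.708%, and the PerR share 0.258% and 2.92%. In the larger table cueR did not pass the threshold for calcium in the mean of 4 days (-0.09 ± 0.22, adjusted p = 0.74), nor did copA (-0.23 ± 0.20, adjusted p = 0.34) or copZ (0.69 ± 0.40, adjusted p = 0.14), and yhdP was lower (-0.87 ± 0.17, adjusted p = 1.6e-04).

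Other splits of the same libraries were counted with edgeR. For the calcium mean, only the real one of 100 splits within days gave as many genes (2629). The others, which mix the media, gave at most 852. For groups of 3 against 3 the 10 splits are too few for a share under 0.05: the real value and the highest other were 1687 and 0 at day 2, 473 and 1 at day 6, 1306 and 0 with age without calcium, and 594 and 0 for cueR.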
